A study of Homo sapiens with 6 samples.

How the data were processed

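RNA of 786-O cells was measured on 6 single-colour Affymetrix arrays, 3 per shRNA, as the labels describe. Total RNA was extracted with Trizol and biotin-labelled complementary RNA was made from it, per the labels' protocols. The arrays were processed in Affymetrix Expression Console, per the submitters' processing notes; its version, its algorithm and any normalization between arrays are not given in the sources used here. The deposited values are intensity values on a linear scale, 1 per probe set and array, between 4.33 and 19770, with none at or below 0. Close medians and quartiles across the 6 arrays are what a normalization between arrays would give, but no source states that step. Background that remains in such values understates the folds of dim genes.

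The table held 49395 probe sets, of which 102 were control probe sets. By the array's annotation, 44994 probe sets had exactly 1 gene symbol, 1832 had several and 2569 had none. Control probe sets and those with several or no symbols were left out of the gene tests, which left 44988. Symbols were updated through Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14, used for names only. Of the 44988 probe sets, 44961 matched and 27 kept the array's name. A gene was read from its probe set with the highest mean over all 6 arrays, which gave 18132 genes, of which 11734 had several probe sets. No genome build was named with the values, so no coordinates are given. Some members of the gene lists are not analysed here: 82 of 1277 different genes were not among the genes tested. The results of 1 of the lists and of the control probe sets for human messenger RNAs are not reported here.

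Before the data were examined, the groups, the tests, 44 gene lists, the rule for named genes and the alternatives were fixed. That plan assumed log2 values as deposited and named the step to take if they were linear, which they were: log2(intensity + 1), with a pseudocount of 1, followed by quantile normalization over all probe sets. Quantile normalization, planned as an alternative, thereby became part of the reported setting. The pseudocount understates the change of dim genes. Groups were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over 18132 genes and a threshold of 0.05. The fit had 4 residual degrees of freedom and 3.63 prior degrees of freedom. For PLEKHO1 the exact two-sided permutation test was run too. Lists were tested with camera in limma, with a preset correlation of 0.01 and adjustment over the 44 lists, and again with an estimated correlation and with fry, whose directional test asks whether the genes of a list move on balance in 1 direction and whose mixed test asks whether they change in either direction. Neither test of fry compares a list with other genes.

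Genes are named by a rule. It takes PLEKHO1, and the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, non-overlapping groups, a higher group mean above the median of all genes and a symbol that does not start with LOC. From each list it takes up to 4 members with the smallest p where camera called the list and otherwise up to 2 members with the smallest p among those that changed. A list with nothing called could be given by its most studied members, which was not needed.

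The steps were tested on simulated data with the spread of these arrays, over 18132 genes, with 50 genes changed at each size. At a log2 change of 0.25 the test recovered 28% of them, at 0.5 92%, and at 1 and 2 100% each. Of 168 calls, 8 were genes that had not been changed. Far fewer genes changed in this simulation than in the data, where 6179 did. Benjamini-Hochberg adjustment depends on that share, so these rates need not hold for the data. In a further simulation, a list shifted by 0.2 was called and 0 of the other lists were. Genes were drawn independently of each other in both simulations. The list simulation therefore cannot show how often lists of genes that move together are called by error.

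The alternatives were centring each array on its median, leaving out the lowest 30% of genes by mean, the mean of all probe sets of a gene, each probe set on its own, a variance trend with robust fitting, array weights, the replicate number as a block, and leaving out each array in turn. After the values were seen to be linear, no normalization between arrays and no pseudocount were added. Background probe sets, tag controls and spike-in controls were used only for the checks of the closing section, and ribosomal RNA controls for these and beside the ribosome biogenesis genes. The sequence of the shRNA and transcript sequences were not used here.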

Results

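Gene expression was measured in 786-O cells, an established human cell line from a clear cell renal cell carcinoma, after delivery by lentivirus of a short hairpin RNA (shRNA), which lowers the messenger RNA it matches. Of the 6 arrays, 3 held RNA of cells with a negative control shRNA (shNC) and 3 held RNA of cells with an shRNA against PLEKHO1 (shPLEKHO1). Each array measured 49395 probe sets, and 18132 genes were tested with 1 probe set each. Median intensity per array ranged from 55.7 to 57.1, so the arrays had close overall brightness. Across genes, log2 values correlated at 0.998 to 0.999 between arrays of a group and at 0.989 to 0.990 between arrays of different groups. The number of arrays limits the precision, and nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. Log2 differences below are shPLEKHO1 minus shNC on the scale of log2(intensity + 1), given ± SE with n = 3 arrays per group, and "rose", "fell" and "changed" refer to an adjusted p under 0.05 in limma.

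PLEKHO1 codes for a pleckstrin homology domain protein, also called CKIP-1, that binds casein kinase 2 and the ubiquitin ligase SMURF1. The comparison asks which transcripts differ when PLEKHO1 is targeted, and the targeted gene itself was examined first. PLEKHO1 intensity was 134.75, 142.63 and 126.15 on the shNC arrays and 110.29, 115.69 and 97.37 on the shPLEKHO1 arrays, and the groups did not overlap. The mean intensity was 135 ± 8.24 (SD, n = 3) with shNC and 108 ± 9.42 (SD, n = 3) with shPLEKHO1. PLEKHO1 fell by 19.9%, with a 95% confidence interval from 9.51% to 29.0% (log2 difference of -0.32 ± 0.08, limma adjusted p = 0.0123). The exact two-sided permutation test of these 3 against 3 arrays gave p = 0.1, the smallest p that this design allows. A single probe set measured PLEKHO1, and 1751 genes fell further than PLEKHO1 did. The highest adjusted p when 1 array was left out was 0.0433, without shNC replicate 2, and over all alternatives it ranged from 0.00264 to 0.0433.

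**Figure D1:**
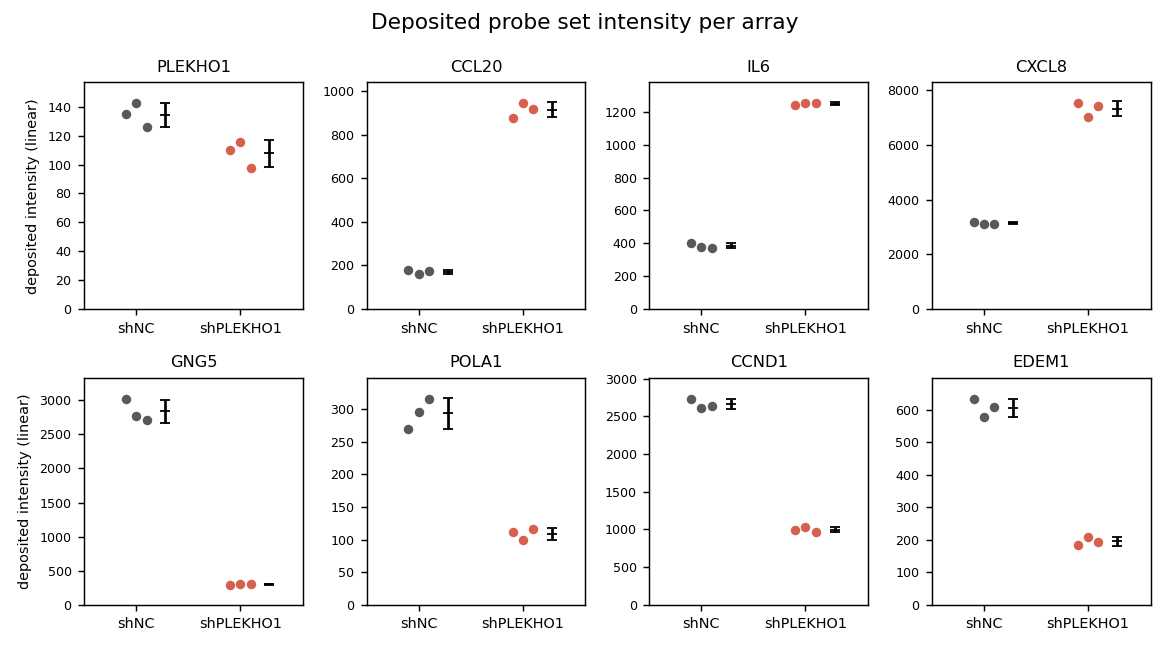
Deposited intensity on a linear scale (y axis, starting at 0) of 8 genes on each of the 3 shNC arrays (grey points) and 3 shPLEKHO1 arrays (red points), with the mean and SD of each group in black beside the points. PLEKHO1 went from 135 to 108 on average, while CCL20, IL6 and CXCL8 were higher and GNG5, POLA1, CCND1 and EDEM1 lower on all shPLEKHO1 arrays.

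The largest rises and falls were taken among changed genes with a mean above the median of all genes. SLN, which codes for sarcolipin, a small inhibitor of the calcium pump of the sarcoplasmic reticulum, was 6.08-fold higher with shPLEKHO1 (log2 difference of 2.60 ± 0.07). CCL20, a chemokine that attracts lymphocytes and dendritic cells, was 5.32-fold higher (2.41 ± 0.05), and its mean intensity went from 171 ± 9.37 to 913 ± 34.0 (SD, n = 3). GLIPR1 was 4.41-fold higher, and all 6 of its probe sets rose. CD274, the immune checkpoint ligand PD-L1, was 3.73-fold higher (1.90 ± 0.12), with 3 of its 4 probe sets past the threshold. The cytokine IL6 was 3.24-fold higher (1.70 ± 0.04), and BCL2A1, an inhibitor of apoptosis, was 3.16-fold higher by its brighter probe set (1.66 ± 0.07); its other probe set was at -0.14, and the mean of both at 0.76. ARHGDIB (1.86 ± 0.06), the protein kinase A scaffold AKAP12 (1.83 ± 0.04), KRTAP2-3 (1.67 ± 0.08) and HOMER2 (1.63 ± 0.05) completed the 10 largest rises.

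Among the falls, GNG5, a gamma subunit of heterotrimeric G proteins, was 9.39-fold lower with shPLEKHO1 (log2 difference of -3.23 ± 0.05), the largest change of all named genes. Its mean intensity was 2835 ± 164 with shNC and 299 ± 9.13 with shPLEKHO1 (SD, n = 3). RAB8B, a small GTPase of vesicle transport, was 6.15-fold lower by its brightest probe set (-2.62 ± 0.05), but of its 4 probe sets 2 fell and 1 rose, and their mean was at -1.15. IFITM3, which restricts the entry of viruses, was 5.13-fold lower (-2.36 ± 0.06), and AKR1B10, an aldo-keto reductase, was 4.89-fold lower (-2.29 ± 0.06). ALYREF, a messenger RNA export factor, was 4.57-fold lower (-2.19 ± 0.09), and FCAMR, an immunoglobulin receptor, was 4.55-fold lower (-2.19 ± 0.16). MAGT1 (-1.98 ± 0.05), JPT2 (-1.98 ± 0.05), the anaphase-promoting complex subunit ANAPC13 (-1.97 ± 0.05) and DGCR2 (-1.93 ± 0.09) followed; the mean over probe sets was smaller for MAGT1 (-1.31), JPT2 (-1.19) and DGCR2 (-0.73). All 20 of these genes had an adjusted p of at most 3.69e-05 in limma (FCAMR), and their groups did not overlap.

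In all, 6179 of 18132 genes changed (34.1%), of which 3284 rose and 2895 fell. Most changes were small: 4872 of the changed genes differed by less than 1.5-fold, and the median absolute log2 difference of changed genes was 0.35. At least 2-fold changes were seen in 317 genes, of which 112 rose and 205 fell. The median SD of a gene within a group was 0.07 in both groups on the log2 scale. The 3 values of 1 group lay entirely above or below those of the other in 8150 genes, 45.0% of those tested, where chance gives 10%. Probe sets of 461 genes went both ways, with at least 1 that rose and 1 that fell, so these genes depend on which probe set is read. With the mean of all probe sets of a gene, 193 genes changed at least 2-fold (69 rose, 124 fell). With each probe set tested on its own, 14858 probe sets changed.

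**Figure D2:**
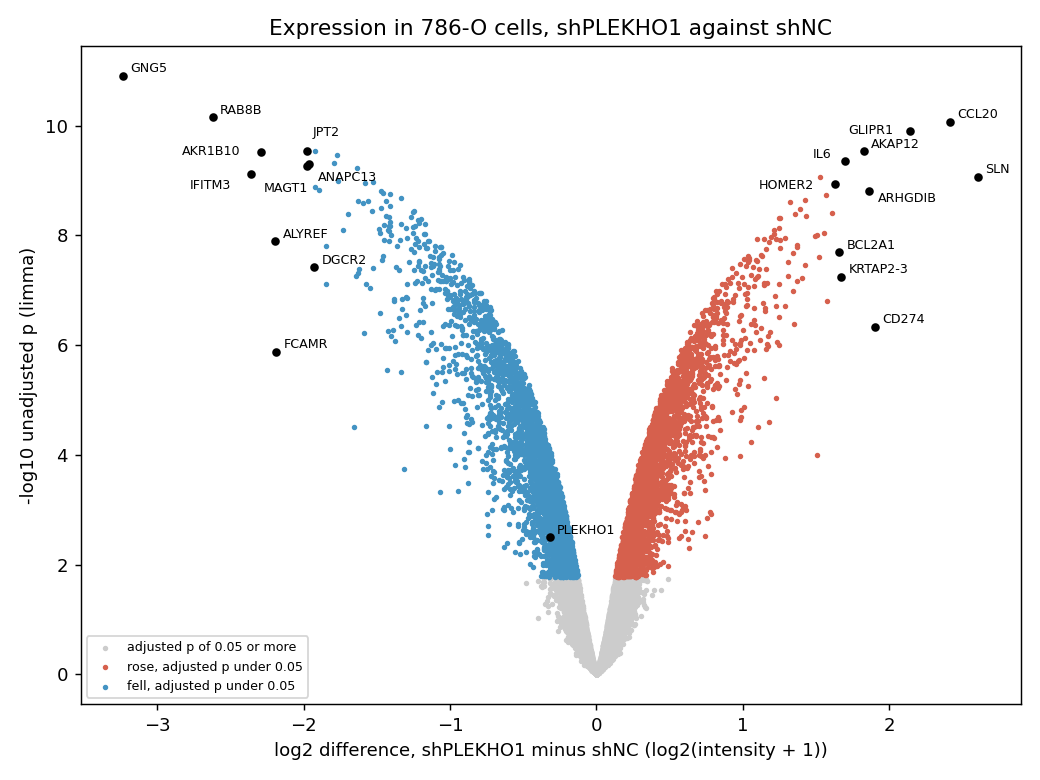
Each point is 1 of 18132 genes, with its log2 difference (shPLEKHO1 minus shNC) on the x axis and -log10 of the unadjusted limma p on the y axis, red for genes that rose, blue for genes that fell and grey for the rest. Black points mark PLEKHO1 and the 10 largest rises and 10 largest falls, of which GNG5 (-3.23) and SLN (2.60) lie outermost, and PLEKHO1 (-0.32) lies close to the centre.

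Genes of DNA replication and the entry into S phase were lower with shPLEKHO1. Of 51 measured members of the list of G1/S and DNA replication genes, 34 fell, 2 rose and 15 did not pass, and the median log2 difference was -0.27. POLA1, the catalytic subunit of DNA polymerase alpha, was 2.68-fold lower (-1.42 ± 0.09), and POLA2, a further subunit of the same enzyme, was 1.69-fold lower (-0.76 ± 0.05). The replication initiation factor MCM10 (-0.94 ± 0.05) and thymidine kinase TK1 (-0.87 ± 0.05) fell too. Adjusted over the list alone, 37 members fell and 2 rose. The list as a set was lower than other genes (camera in limma, adjusted p = 1.47e-10), and of the 9 lists called among 44 it was the only one called with an estimated correlation (adjusted p = 0.0459). A lost call need not mean a higher correlation. The estimate was below the preset of 0.01 for the NF-kB (0.0087), ATF4 (-0.0091), chaperone (-0.0218), ligase (-0.0336) and binding partner (-0.012) lists. It was above for the immediate early (0.0606), metallothionein (0.0698) and ribosome biogenesis (0.0117) lists.

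Other cell cycle lists were not called as sets. Of 59 genes of G2/M and mitosis, 22 fell and 12 rose (adjusted p = 0.110), among them the topoisomerase TOP2A (-1.01 ± 0.05) and the kinesin KIF14 (-0.95 ± 0.05), which both fell. Of 17 CDK inhibitors and G1 cyclins, 6 fell and 1 rose (adjusted p = 0.0527), and this list was called with median centring (adjusted p = 0.0318), with a variance trend (0.0226) and without normalization between arrays (0.0336), in a range of adjusted p from 0.0226 to 0.270. CCND1, the cyclin that drives cells through G1, was 2.66-fold lower (-1.41 ± 0.04), and all 4 of its probe sets fell. The CDK inhibitor CDKN1C was 2.28-fold lower (-1.19 ± 0.06). Of 38 replication-dependent histones, 5 rose and 2 fell (adjusted p = 0.861), with H2BC12 at 0.75 ± 0.04 and H2BC4 at 0.29 ± 0.05. Each of these genes had 2 probe sets, of which 1 rose. The other was at 0.11 for H2BC12 and 0.19 for H2BC4. H2BC4 was dim, with a mean intensity of 12.4 with shNC and 15.5 with shPLEKHO1. A background probe set (GC16) read 13.3 and 13.9. The median of the histones was below 0 while their mean and test were above it. Adjusted over each list alone, 36 G2/M genes, 7 CDK inhibitors and G1 cyclins and 4 histones changed.

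Genes that NF-kB induces, chemokines and cytokines included, were higher with shPLEKHO1. Of 32 measured members 14 rose and 4 fell, with a median log2 difference of 0.14 (camera adjusted p = 0.002, and adjusted p = 0.167 with an estimated correlation). CCL20 and IL6 had the smallest p in the list. CXCL8, the neutrophil chemokine interleukin 8, was 2.34-fold higher (1.23 ± 0.05) and reached a mean intensity of 7318 ± 271 (SD, n = 3). BCL2A1, the other member named by rule, is given above among the largest rises. Immediate early and AP-1 genes, which respond early to growth factors and stress, rose in 10 of 21 cases and fell in 2 (median 0.18, camera adjusted p = 0.0186, and adjusted p = 0.296 with an estimated correlation). Examples were SRF (0.95 ± 0.05), IER3 (0.87 ± 0.05), ATF3 (0.78 ± 0.06) and KLF6 (0.63 ± 0.05). Adjusted over the list alone, 20 NF-kB genes and 12 immediate early genes changed.

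Genes of the endoplasmic reticulum and of amino acid stress were lower. Of 24 endoplasmic reticulum chaperones and other unfolded protein response genes, 12 fell and 2 rose, with a median of -0.21 (camera adjusted p = 0.0021, and adjusted p = 0.166 with an estimated correlation). EDEM1, which marks misfolded glycoproteins for degradation, was 3.09-fold lower by its brightest probe set (-1.63 ± 0.05), and all 5 of its probe sets fell, with a mean of -0.71. The chaperone HYOU1 (-1.06 ± 0.04) and MANF (-0.67 ± 0.05) fell as well. CRELD2 fell by its brighter probe set (-1.21 ± 0.08), while its other probe set was at 0.11 and the mean of both at -0.55. Of 36 target genes of ATF4, the transcription factor of the integrated stress response, 18 fell and 4 rose, with a median of -0.16 (camera adjusted p = 0.0017, and adjusted p = 0.166 with an estimated correlation). The serine synthesis enzyme PSPH (-1.28 ± 0.06), the mTOR inhibitor DDIT4 (-1.17 ± 0.06) and asparagine synthetase ASNS (-0.73 ± 0.04) fell. STC2 rose by its brightest probe set (0.93 ± 0.04), while another of its 3 probe sets fell, and the mean of its probe sets did not pass (0.11, adjusted p = 0.0647, in a range of 4.25e-12 to 0.0647 over the alternatives). Adjusted over the list alone, 15 chaperone genes and 22 ATF4 genes changed.

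Genes of ribosome production were higher. Of 34 nucleolar and other ribosome biogenesis genes, 20 rose and 4 fell, with a median of 0.24 (camera adjusted p = 0.000335, and adjusted p = 0.166 with an estimated correlation). The rises included HEATR1 (0.80 ± 0.05), which acts in the processing of ribosomal RNA precursors and of which 1 of 4 probe sets rose, the RNA polymerase subunit POLR1C (0.72 ± 0.05) and RRS1 (0.60 ± 0.05). TCOF1, a nucleolar factor of ribosomal RNA transcription, went the other way (-0.62 ± 0.04). On the same arrays, 2 of the 3 control probe sets for 28S ribosomal RNA were higher with shPLEKHO1, by 1.06 ± 0.05 and 0.74 ± 0.08 on the log2 scale. The third did not pass (0.09, limma adjusted p = 0.407). More ribosomal RNA in the cells cannot be told apart here from more of it carried into the labelled pool. Of 49 cytosolic ribosomal proteins, 1 rose and 1 fell (adjusted p = 0.942). RPL14 was 2.03-fold lower (-1.02 ± 0.05), with 4 of its 5 probe sets down, and RPL13 was higher (0.23 ± 0.06) but did not pass without shNC replicate 1 (adjusted p = 0.0511) or without shPLEKHO1 replicate 2 (0.0510), in a range from 0.000118 to 0.0511 over the alternatives. For the ribosomal proteins the mean was below 0, and the median and the test were above it. Adjusted over the list alone, 25 biogenesis genes and 1 ribosomal protein gene changed.

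Metallothioneins and genes of the metal response rose in 6 of 13 cases and fell in 1, with a median of 0.21 (camera adjusted p = 0.0106, and adjusted p = 0.270 with an estimated correlation). The metallothionein MT1X (0.76 ± 0.07), the metal-sensing transcription factor MTF1 (0.70 ± 0.06) and the metal transporters SLC39A14 (0.71 ± 0.05) and SLC30A1 (0.48 ± 0.05) rose. For SLC39A14, 3 of 4 probe sets rose. Adjusted over the list alone, 7 of these genes changed.

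Proteins known to bind PLEKHO1 formed a list of 16 measured genes, of which 8 rose and 1 fell, with a median of 0.18 (camera adjusted p = 0.0438, and adjusted p = 0.270 with an estimated correlation). The transcription factor JUN (0.53 ± 0.05), the ubiquitin ligase SMURF1 (0.63 ± 0.06) and the proteasome activator PSME3 (0.46 ± 0.05) rose, and CSNK2A1, a catalytic subunit of casein kinase 2, fell (-0.51 ± 0.05). This call was lost in 7 of 15 alternatives with camera, among them without shNC replicate 2 (adjusted p = 0.0584), without shPLEKHO1 replicate 2 (0.0799) and without shPLEKHO1 replicate 3 (0.0514), in a range of camera adjusted p from 0.0209 to 0.270. Ubiquitin ligases of the NEDD4, SMURF and cullin families rose in 13 of 26 cases and fell in 3, with a median of 0.14 (camera adjusted p = 0.0186, and adjusted p = 0.225 with an estimated correlation). NEDD4 was 2.25-fold higher (1.17 ± 0.08), CUL4A rose (0.54 ± 0.05), and the muscle F-box protein FBXO32 fell (-0.61 ± 0.06). NEDD4L rose by its brightest probe set (0.74 ± 0.04), but of its 7 probe sets 4 rose and 2 fell, and their mean did not pass (0.02, adjusted p = 0.697, in a range from 5.32e-10 to 0.697). The ligase list was not called without shPLEKHO1 replicate 2 (adjusted p = 0.0522), without dim genes (0.0629) or with the mean of probe sets (0.349), in a range of camera adjusted p from 0.0136 to 0.349. Adjusted over the list alone, 10 binding partners and 16 ligase genes changed.

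**Figure D3:**
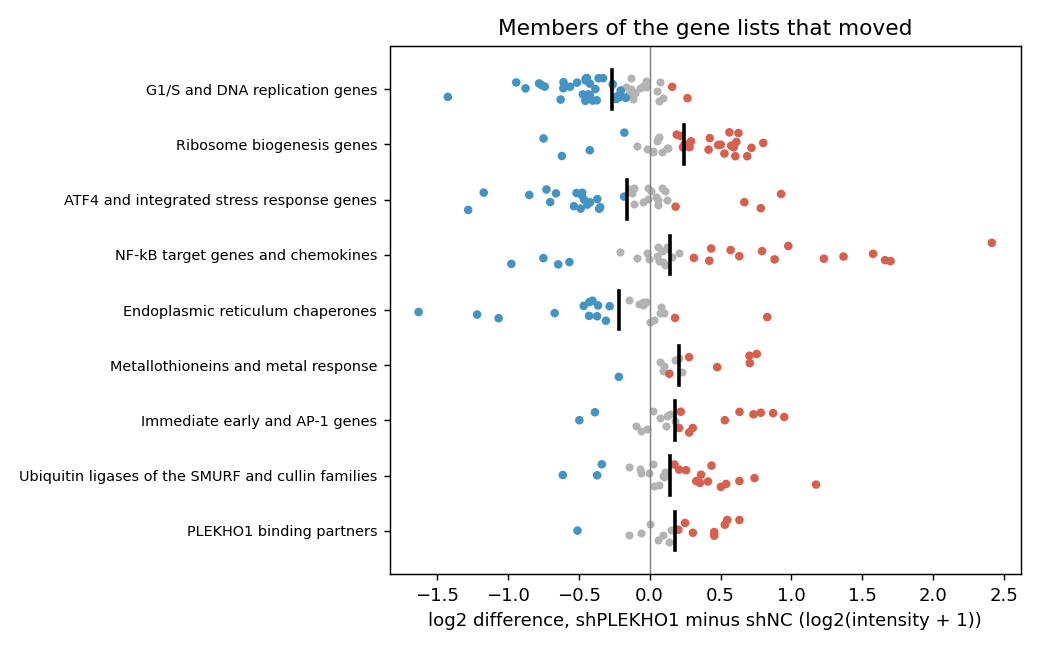
Log2 differences (x axis, shPLEKHO1 minus shNC) of the members of the 9 gene lists called by camera, 1 line per list, with red for members that rose, blue for members that fell, grey for the others and a black bar at the median of the list. The median lies left of 0 in the replication (-0.27), ATF4 (-0.16) and chaperone (-0.21) lists and right of 0 in the other lists; vertical scatter within a line has no meaning.

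The signalling pathways tied to PLEKHO1 in the literature were not called as sets. Of 30 Hippo pathway components 11 rose and 3 fell (median 0.13, camera adjusted p = 0.0918). FRMD6, an upstream regulator of the pathway, was higher (0.59 ± 0.04). NF2, the merlin tumour suppressor, was 1.42-fold lower (-0.50 ± 0.04), with 5 of its 7 probe sets down. Of 22 target genes of the Hippo effectors YAP and TAZ, 7 rose and 7 fell (adjusted p = 0.861). Among them IGFBP3 was 2.39-fold lower (-1.26 ± 0.04) and ASAP1 was 2.26-fold lower (-1.18 ± 0.04). For this list the mean was above 0 and the median and the test were below it. Of 30 JNK and p38 MAPK components 10 rose and 7 fell (adjusted p = 0.861). The phosphatase DUSP1, which switches these kinases off, was 2.26-fold higher (1.18 ± 0.05), and the kinase MAP3K5 was 2.65-fold lower (-1.40 ± 0.09). Here the median was below 0 and the mean and the test were above it. Adjusted over each list alone, 15 Hippo components, 16 YAP and TAZ target genes and 17 JNK and p38 components changed.

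Feedback genes of ERK signalling rose in 9 of 19 cases and fell in 6 (adjusted p = 0.474). SPRY2, an inhibitor of receptor tyrosine kinase signalling, was 2.01-fold higher (1.01 ± 0.05), while CCND1, a member of this list too, fell. Of 27 components of the PI3K, AKT and mTOR pathway 12 rose and 5 fell (adjusted p = 0.135). RPTOR, the scaffold of mTOR complex 1, rose (0.71 ± 0.05), with 2 of its 6 probe sets past the threshold. The kinase GSK3B fell by its brighter probe set (-1.12 ± 0.06), whereas its other probe set rose (0.55), and the mean of both was at -0.29. Of 34 Wnt pathway and target genes 14 fell and 7 rose (adjusted p = 0.110). The feedback inhibitor AXIN2 fell by its brightest probe set (-0.79 ± 0.05), the only 1 of its 3 probe sets that fell. Of 23 Notch pathway genes 4 rose and 5 fell (adjusted p = 0.942), with MAML2 at 0.93 ± 0.05 and ADAM17 at -0.61 ± 0.05 (3 of 4 probe sets fell). Of 20 target genes of TGF-beta and BMP signalling, 6 rose and 7 fell (adjusted p = 0.729), with the BMP antagonist NOG at 0.55 ± 0.05 and the BMP target gene ID1 at -0.60 ± 0.05. Hypoxia-inducible factor target genes rose in 8 of 31 cases and fell in 9 (adjusted p = 0.822), and the mitophagy receptor BNIP3L was 2.73-fold lower (-1.45 ± 0.06), with all 6 of its probe sets down. For the Notch, TGF-beta and hypoxia lists, the sign of the test was negative and that of the median positive; the mean was positive for Notch alone. With p adjusted over the list alone, 15 ERK feedback, 17 PI3K, 21 Wnt, 9 Notch, 14 TGF-beta and BMP and 17 hypoxia genes changed.

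Target genes of p53 went both ways, with 9 of 30 that rose and 12 that fell (adjusted p = 0.729). GADD45A, a stress-induced regulator of growth arrest, was 2.06-fold higher (1.04 ± 0.05). The cytokine GDF15 was 2.32-fold lower (-1.22 ± 0.08), with 3 of its 5 probe sets down and the highest at 0.10. Of 33 apoptosis regulators 11 rose and 9 fell (adjusted p = 0.681). BCL2A1 rose by 1 of its 2 probe sets, and MCL1, an inhibitor of apoptosis as well, fell by its brightest probe set (-0.76 ± 0.05), with 4 of its 6 probe sets down and 1 up. Interferon-stimulated genes rose in 9 of 41 cases and fell in 13 (adjusted p = 0.607). PLSCR1 was 2.65-fold lower (-1.41 ± 0.05). IFIT5 was 1.56-fold higher by its brighter probe set (0.64 ± 0.05), while its other probe set was at -0.03. Of 19 genes of antigen presentation 4 rose and 4 fell (adjusted p = 0.542), with the class I molecules HLA-C (-0.87 ± 0.05) and HLA-B (-0.40 ± 0.04) both lower. Of the 3 probe sets of HLA-B, 2 fell and the highest was at 0.20. On their own, that is adjusted over the list alone, 21 p53 target genes, 22 apoptosis regulators, 26 interferon-stimulated genes and 9 antigen presentation genes changed.

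Markers of cell identity were not called as sets. Of 22 mesenchymal genes 5 rose and 2 fell (adjusted p = 0.545), with the smooth muscle actin ACTA2 2.19-fold higher (1.13 ± 0.05; 1 of 3 probe sets rose, and their mean was at 0.43) and the transcription factor ZEB2 1.52-fold higher (0.60 ± 0.06). Of 25 epithelial genes 4 rose and 5 fell (adjusted p = 0.416). The epithelial transcription factor ELF3 was 2.00-fold lower, with all 3 of its probe sets down, and the adhesion molecule EPCAM was 1.86-fold lower (-0.89 ± 0.07). Proximal tubule markers, of the kidney cells that clear cell carcinoma resembles, fell in 6 of 26 cases and rose in 2 (adjusted p = 0.221), and both the cadherin CDH6 (-0.96 ± 0.08) and the aminopeptidase ANPEP (-0.58 ± 0.05) fell. Endothelial, leukocyte, fibroblast and keratin markers changed in few cases. A difference between the groups cannot show whether such cells were present. Of 19 endothelial markers 1 rose and 1 fell (adjusted p = 0.746; ROBO4 at 0.89 ± 0.07, EGFL7 at -0.35 ± 0.06). Of 20 leukocyte markers 3 rose and 1 fell (adjusted p = 0.416). LAPTM5 rose by 1 of its 2 probe sets (0.67 ± 0.05, with the other at 0.13), and LCP1 rose too (0.61 ± 0.05). Of 16 fibroblast markers LUM alone rose (0.81 ± 0.07) and none fell (adjusted p = 0.861), and of 10 keratin and squamous markers 2 rose (adjusted p = 0.474; KRT15 at 0.91 ± 0.07, PERP at 0.32 ± 0.05). PERP did not pass with the mean of its probe sets (0.08, adjusted p = 0.227, in a range from 8.82e-06 to 0.227). When adjusted over the list alone, 7 mesenchymal, 9 epithelial, 9 proximal tubule, 2 endothelial, 4 leukocyte, 1 fibroblast and 2 keratin genes changed.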

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

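The tests of spike-in, tag, background and ribosomal RNA probe sets, of array correlations and of the share of falling genes were chosen only after the results were seen, and the counts over other splits were planned before. Of probe sets that the gene tests do not use, some differed between shPLEKHO1 and shNC: among 2473 probe sets without a gene symbol 369 rose and 333 fell, and among 1832 with several symbols 264 rose and 241 fell. Control probe sets for ribosomal RNA, which are not used in the gene tests either, were higher with shPLEKHO1 by 1.06 (28S, 5' end), 0.74 (28S, middle), 0.31 (18S, middle) and 0.16 (18S, 5' end) on the log2 scale. The 3' probe sets of both did not pass, with 0.09 for 28S (adjusted p = 0.407 in limma) and 0.03 for 18S (0.660).

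Of the 10 splits of the 6 arrays into 3 and 3, 1 gave 6179 changed genes or more, the real one, and the highest of the other splits gave 0. The same held for genes changed at least 2-fold, with 1 of 10 splits at 317 or more and 0 as the highest other value, and for lists, with 1 of 10 splits at 9 or more and 2 as the highest other value. These 10 splits are too few for a share under 0.05. Each of the other splits mixed arrays of both groups, so the difference between the groups added to its spread and made calls unlikely. Their counts of 0 changed genes therefore say little. Most of the other splits still called a list.

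PLEKHO1 fell by 19.9%, while 1751 genes fell further. A wrong group label on 1 or 2 arrays is argued against: 0 of the 6 arrays lay closest to an array of the other group. Signal close to background stays open, because a background of 81.05 under the PLEKHO1 probe set would hide a fall by 50%; 18 of 23 background probe sets lay below that, the brightest reached 2200, and the GC content of the PLEKHO1 probes was not known here. Direct lowering of other transcripts by the shRNA stays open too: 64.67% of the genes changed at least 2-fold fell, against 45.9% of those changed less, but a search for seed matches was not made without the sequences. A response to a modest loss of PLEKHO1 may also explain the other changes and was not tested, since a single shRNA against PLEKHO1 was used.

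With shPLEKHO1, 34.1% of the genes changed, most of them by little. Labelling or hybridisation that differed between the groups could shift many genes. Of 45 spike-in probe sets 0 passed, and their median absolute difference was 0.05, against 0.35 for changed genes. The changed genes were selected by the test and the spike-ins were not, so these medians are not alike. However, 2 of 17 tag control probe sets (-0.18 and -0.20) and 1 of 23 background probe sets (0.18) passed. Differences of background probe sets mostly grew with GC content: 0.01 at GC13, 0.07 at GC17, 0.14 at GC21, 0.19 at GC24 and 0.18 at GC25. Labelling or hybridisation differences stay open, since this shift followed GC content and the difference plus 2 SE reached 0.38 in 1 spike-in. With the bound taken for the spike-in of largest difference alone (0.28) it would have lain below 0.35; both bounds had been seen, and the wider was kept. Culture or RNA extraction shared within each group cannot be told apart from the shRNA, because the labels do not say that replicates were separate cultures and arrays of a group correlated at 0.99791 or more.

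The rise of 28S ribosomal RNA signal was weighed too. A general rise of GC-rich background is argued against, since the largest rise of a background probe set was 0.19, and the highest rise plus 2 SE (0.33) lay below the lower 28S rise less 2 SE (0.59). The largest rise of a spike-in was 0.15, or 0.28 with 2 SE added, also below 0.59. Quantile normalization removes a difference shared by all probe sets, so the spike-ins cannot test for a shared labelling or hybridisation difference. The spike-ins are not ribosomal RNA, so they cannot tell whether ribosomal RNA alone was labelled more. More ribosomal RNA carried into the labelled pool may explain the rise and cannot be told apart from more ribosomal RNA in the cells: 2 of 3 18S probe sets rose too, by up to 0.3068, and neither value separates them.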

How the results depend on the processing

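Tests without normalization between arrays and without a pseudocount were chosen only after the values were seen; the other alternatives were planned, and planned quantile normalization is part of the reported setting. No named gene and no called list turned direction; the mean of 5 lists that were not called (p53, proteasome, integrin, Notch, JNK and p38) changed sign in some alternative. The fold of 11 named genes moved by over 1.5 times with the mean of probe sets, as given beside each. PLEKHO1 stayed below an adjusted p of 0.05 in all 15 alternatives, with log2 differences from -0.37 to -0.25 when 1 array was left out. Leaving out 1 array gave 5227 to 5701 changed genes (2767 to 3040 rose, 2460 to 2661 fell), 313 to 320 changed at least 2-fold (108 to 117 rose, 196 to 212 fell) and 7 to 9 lists called. Median centring gave 5805 changed genes, array weights 6447, a variance trend 6682 and the filter on dim genes 6335 of 12692. With the mean of all probe sets, 193 genes changed at least 2-fold (69 rose, 124 fell), and 52 of the reported changed genes passed with the other sign. This alternative differs only in the probe sets read for a gene, and 461 genes had probe sets that went both ways. Why probe sets of a gene differ was not tested. Each probe set on its own gave 14858 calls (7794 rose, 7064 fell), 854 of them at least 2-fold (289 rose, 565 fell), over more probe sets than genes. Camera with an estimated correlation called 1 list, the G1/S list, which kept its call in 15 of 15 alternatives with camera; fry called 34 lists in its directional and 44 in its mixed test. Of lists not called, cholesterol biosynthesis passed with the mean of probe sets (adjusted p = 0.0416, in a range up to 0.270); the cause was not tested. With the replicate block 5244 genes were called, 5157 of them shared with the reported calls, PLEKHO1 was at -0.32 and 9 lists were called. Deviations of same-numbered arrays correlated at -0.163, -0.156 and -0.047, and no array correlated best with its own number. These values showed no pairing by number, but the labels do not say how the replicates were made. Dim signals are limited by background, which reached 2200 in the most GC-rich background probe set.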

Other observations

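Lipid genes moved in both directions. Of 19 cholesterol biosynthesis genes 9 fell and 4 rose (camera in limma, adjusted p = 0.110), and DHCR7, the enzyme of the last step to cholesterol, was 2.74-fold lower (log2 difference of -1.45 ± 0.05, SE, n = 3 arrays per group), while IDI1 was 1.49-fold lower. Of 26 genes of fatty acid synthesis and lipid storage 6 rose and 6 fell (adjusted p = 0.858); the desaturase SCD was 2.52-fold lower (-1.33 ± 0.05), and the elongase ELOVL6 was 1.43-fold higher (0.51 ± 0.04). Glycolysis genes rose in 6 of 21 cases and fell in 7 (adjusted p = 0.858), with PFKFB3 (-0.77 ± 0.05) and pyruvate kinase PKM (-0.72 ± 0.05) among those that fell. For both of these lists the median was above 0 and the mean and test below it. Of 50 subunits of oxidative phosphorylation 13 rose and 5 fell (adjusted p = 0.327), and the complex I subunits NDUFA9 (-0.96 ± 0.06) and NDUFC2 (-0.49 ± 0.05) fell. NRF2 target genes fell in 9 of 24 cases and rose in 4 (adjusted p = 0.474), with AKR1B10 4.89-fold lower and the sulfiredoxin SRXN1 2.12-fold higher (1.08 ± 0.05). Adjusted over each list alone, 14 cholesterol, 15 fatty acid, 13 glycolysis, 20 oxidative phosphorylation and 14 NRF2 genes changed.

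The lists of matrix, adhesion, proteasome, lysosome and heat shock genes were not called. The matrix glycoprotein tenascin C, TNC, was 2.97-fold higher (1.57 ± 0.05), and all 4 of its probe sets rose, while the proteoglycan VCAN was 1.77-fold lower (-0.82 ± 0.04), with all 9 probe sets down. Of 45 extracellular matrix genes 7 rose and 7 fell (adjusted p = 0.858; mean above 0, median and test below). Of 31 integrin and focal adhesion genes 7 rose and 11 fell (adjusted p = 0.746; median above 0, mean and test below), with FERMT2 at 0.81 ± 0.05 and TNS3 at -0.89 ± 0.05. In protein turnover, the proteasome subunit PSMB6 was 2.18-fold lower (-1.13 ± 0.05) and PSMD12 was 1.77-fold higher (0.82 ± 0.04), and of 27 subunits 9 rose and 5 fell (adjusted p = 0.416). Of 40 lysosome and autophagy genes 12 rose and 13 fell (adjusted p = 0.416), with WIPI2 2.45-fold lower (-1.29 ± 0.05) and ATP6V1A 1.66-fold lower. Of 19 cytosolic heat shock genes 7 rose and 1 fell (adjusted p = 0.178), with HSPB8 at 0.72 ± 0.06 and HSPH1 at 0.56 ± 0.05. Adjusted over each list alone, 14 matrix, 21 integrin, 14 proteasome, 28 lysosome and 8 heat shock genes changed.

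RPL14 fell by 1.02 on the log2 scale. The other 48 measured cytosolic ribosomal proteins had a median of 0.0167 (SD 0.06) and lay between -0.13 and 0.23.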
